A study of Homo sapiens with 16 samples.

How the data were processed

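Gene expression was measured by RNA sequencing of colonic biopsies from healthy volunteers and from patients with post-infection irritable bowel syndrome (PI-IBS), a disorder of bowel habit and pain that begins after an infection of the gut. Per the labels' protocols, biopsies were flash frozen in liquid nitrogen, RNA was extracted with the miRNeasy kit, and stranded mRNA libraries with unique dual indexes were pooled and sequenced as paired reads on a NovaSeq. The labels put each of the 16 libraries in 1 of 3 groups: 6 High PA and 5 Low PA libraries from patients, and 5 libraries from healthy individuals, also labelled Low PA and called Healthy here. The labels do not spell out PA. It is read here as proteolytic activity in the gut, from general knowledge of work on this disease, and no calculation depends on that reading. Replicate numbers follow the order of the samples in the series and only name a library, so nothing pairs libraries across groups.

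The deposited table gives, per gene, raw counts and FPKM values made by the authors. Per the submitters' processing notes, bcl2fastq, STAR 2.6.1c, Subread 1.5.1 and featureCounts were used with the genome build hg38. The release of the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical copies may therefore be split, shared or lost, and the levels of such genes are uncertain. In the exons of a GENCODE annotation of hg38, 28 of the 86 genes that the rule takes overlap another tested gene, 13 on the same strand and 16 on the opposite strand. These are A2M, ACP5, CCDC183, ENOSF1, ETV4, F2RL2, FTH1, GATD3B, GNGT2, LEPR, MARVELD3, MUC1, MUC17, MUC20, MUC3A, PAX8, PLTP, PSCA, RGS5, SERPINA3, SNHG32, SPINT1, UGDH, UGT1A1, UGT1A6, UGT1A8, UGT1A10 and ZNF839. The table holds 64253 genes, of which 3974 lie on alternate haplotype contigs, so genes with copies there, such as those of the MHC region, are uncertain too. The gene name was blank for 20449 genes, and 19424 of these were named by their Ensembl identifier from a reference table.

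Counts as deposited were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter by group, robust dispersion estimates, and all 16 libraries in 1 fit with 3 groups. The filter left 19648 genes, 15452 of them protein-coding. XIST, TSIX and genes annotated on chromosome Y, 617 in all, were left out of every table and test. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The comparisons were High PA against Healthy, High PA against Low PA, Low PA against Healthy, and the average of both patient groups against Healthy. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of the F statistic. The authors' FPKM values entered only an alternative test, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), with limma 3.58.1. Levels are given as CPM, the counts of a gene scaled by the library total and the TMM factor to a common library size.

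Lists of genes for cell types, barrier, protease and stress functions were fixed before the data were examined, 51 lists with 630 symbols, all of which were found in the table. The 50 lists with at least 3 tested members were tested with fry, a rotation test on the edgeR fit, adjusted over the lists within a comparison. Members were also adjusted over the list alone. That adjustment takes no account of the number of lists or comparisons, so some members may pass it by chance. The rotation test asks whether a list's genes move, on balance, one way, and does not compare them with other genes. Camera, which does, was run as an alternative with a preset correlation of 0.01 and with an estimated one.

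Genes were named by a rule fixed before the data were examined, except that the examples from lists outside the 7 given here were chosen after their values were seen. In each pairwise comparison it takes up to 12 called protein-coding genes per direction with the smallest p and a median of at least 1 CPM in the higher group. Where fewer than 6 pass, genes with the smallest p fill the direction up to 6 and are given as values that did not pass. For PI-IBS against Healthy the numbers are 5 and 3. From the 7 lists of tight junction, serine protease, protease inhibitor, protease-activated receptor, mast cell, cell-surface mucin and glucuronidation genes, and from any called list, up to 4 members with the smallest p are added, of which 1 is not reported here. Genes on a preset list of those whose level follows sex, germline genotype or a lymphocyte clone are counted but not named. Genotypes were not examined, so germline effects on the named genes are not excluded. That exception was extended, after the data were seen, to X-linked genes known to escape X inactivation: 1 gene was passed over in High PA against Healthy and the next by p took its place. It was also extended to a miRNA gene that lies among the immunoglobulin lambda genes. Because the genes with the smallest p were picked in these same libraries, counts of libraries above or below a group mean follow in part from that choice.

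Total counts ranged from 22241852 to 33448480 per library, and the biological coefficient of variation, from the common dispersion of 0.118, was 34.3%. The main test was tested on simulated counts with the real means, depths and dispersions, in which 100 genes were changed 2-fold and 100 genes 4-fold among 19648. A further list of genes was raised 2-fold to test fry. For High PA against Healthy it recovered 41% of the 2-fold and 87% of the 4-fold changes, for High PA against Low PA 47% and 80%, and for Low PA against Healthy 47% and 72%. It made 7, 9 and 3 false calls in these 3 simulations. Each gene was drawn independently, so trends that genes share within a real library were absent. Recovery and false calls in the real libraries may therefore differ from these values. Per-library trends on gene length and GC percent were Spearman correlations across 12015 protein-coding genes above a mean of 2 log2 CPM. Length was taken from the deposited table and GC percent from the longest reference transcript, available for 97.9% of the genes tested. Library measures were compared by exact permutation tests, two-sided, over every split of the libraries of 2 groups, with 24 tests adjusted together.

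Alternatives fixed before the data were examined were the size factors of DESeq2, no filter and a stricter filter of 1 CPM in at least 5 libraries, DESeq2 1.42.0, limma voom with sample quality weights, a fit of only the groups compared, dispersions without robust estimates, a covariate for biopsy composition, 1 surrogate variable from sva 3.50.0, the FPKM tests, a looser threshold of 0.1, and leaving out each library in turn. The composition covariate is the mean log2 CPM of absorptive colonocyte genes minus that of smooth muscle and fibroblast genes. Alternatives chosen after seeing the data were a correction of each library for splines of length and GC percent, that correction with weighted voom, voom without weights, a covariate for the immediate early genes, and a fit without 5 libraries high in these genes. No pair of libraries of a group agreed within sampling noise: the smallest chi-square per degree of freedom between libraries was 59.8, in Healthy.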

Results

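RNA sequencing profiles of 16 colonic biopsies were compared to find which genes differ in the colon of patients with post-infection irritable bowel syndrome (PI-IBS), and whether patients of the High PA group differ from those of the Low PA group. The data comprised 6 High PA, 5 Low PA and 5 Healthy libraries. Each is taken as 1 volunteer, as the series describes its groups, although the labels do not number the volunteers. Total counts were 28041897, 28893660, 25298160, 29208741, 23755825 and 24766701 in High PA replicates 1 to 6. They were 24311170, 25316908, 30386176, 30199261 and 32142628 in Low PA replicates 1 to 5. In Healthy replicates 1 to 5 they were 26849144, 28843385, 30313050, 33448480 and 22241852. At this depth a gene at 1 CPM had more than 20 counts in each library, and the spread between biopsies rather than counting set the error of most values.

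Markers of colonocytes, connective tissue and immune cells were measured beside the disease comparisons, because a biopsy mixes cell types. The colonocyte minus stroma score was 3.02 ± 0.536 (SD, n = 6) log2 units in High PA, 2.89 ± 0.188 (SD, n = 5) in Low PA and 3.02 ± 0.62 (SD, n = 5) in Healthy. The share of mitochondrial counts was 20.0% ± 4.19 (SD, n = 6), 17.8% ± 3.19 (SD, n = 5) and 23.1% ± 7.63 (SD, n = 5) in the same order. Libraries also differed in how expression followed the length and GC percent of genes. The length correlation across genes averaged 0.169 ± 0.278 (SD, n = 6) in High PA, -0.0424 ± 0.310 (SD, n = 5) in Low PA and -0.240 ± 0.207 (SD, n = 5) in Healthy. High PA and Healthy differed by 0.409 (two-sided exact permutation p = 0.0303, adjusted p = 0.182), which did not pass. The GC correlation averaged -0.179 ± 0.352 (SD, n = 6) in High PA, -0.110 ± 0.386 (SD, n = 5) in Low PA and 0.304 ± 0.143 (SD, n = 5) in Healthy. High PA and Healthy differed in it by -0.483 (two-sided exact permutation p = 0.026, adjusted p = 0.182). Genes are not independent replicates, so each correlation describes a library. Immediate early genes such as FOS and EGR1, which cells switch on within minutes of a stimulus, ranged from 3.6 to 7.76 mean log2 CPM between libraries. Their group means were 5.19 ± 1.66 (SD, n = 6), 4.67 ± 1.29 (SD, n = 5) and 5.60 ± 1.95 (SD, n = 5) in the same order.

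**Figure D1:**
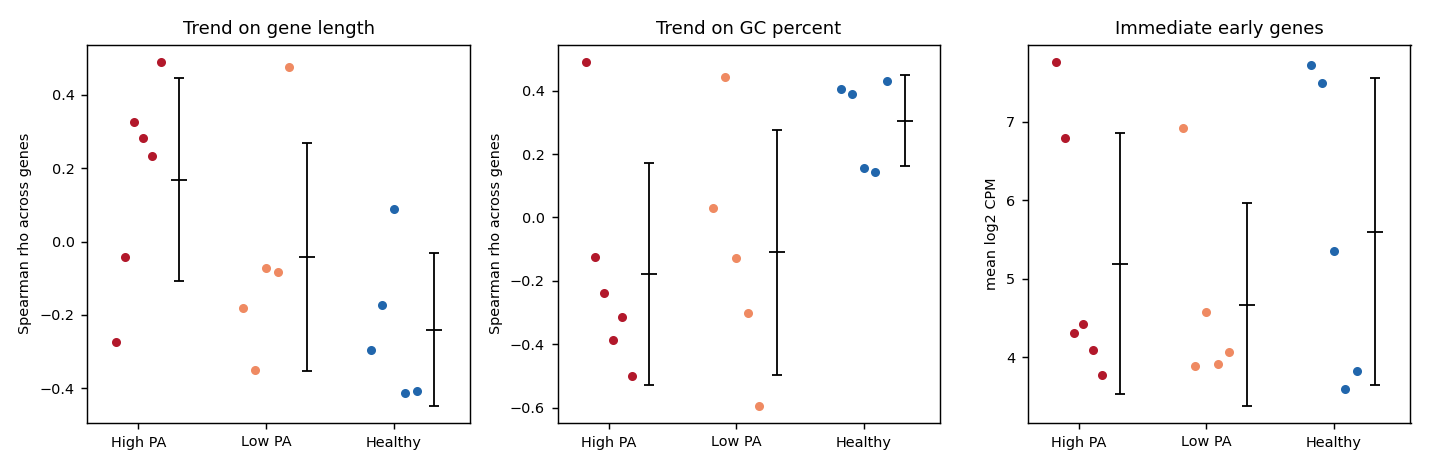
Each point is 1 library in the group named on the horizontal axis, and the bars give the group mean and SD. The vertical axes give the Spearman correlation across genes between expression relative to the mean of all libraries and gene length (left) or GC percent (middle), and the mean log2 CPM of the immediate early genes (right). The length correlation averages 0.169 in High PA and -0.240 in Healthy, and immediate early genes reach 7.76 in High PA and 7.72 in Healthy.

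The comparison of High PA with Healthy asks what is changed in patients with high PA, with the healthy biopsies as baseline. The genes with the smallest p were higher for LEPR, SEMA3C, INVS, ADAMTSL3, ZDBF2 and RGS5 and lower for PSCA, ETV4, ME3, FTH1, GATD3B and SNHG32, and none of them passed the adjusted threshold (edgeR quasi-likelihood test, adjusted p = 0.387 for each). LEPR, the leptin receptor, on chromosome 1 from 65420652 to 65641559 of hg38, was at 5.62 ± 1.69 CPM (SD, n = 6) in High PA and 1.97 ± 0.352 CPM (SD, n = 5) in Healthy. This is a fold of 2.85 (log2 1.51, SE 0.32), with 6 of 6 High PA libraries above the Healthy mean. PSCA, a small surface protein of epithelia, on chromosome 8 from 142670308 to 142682724, was at 0.401 ± 0.544 CPM (SD, n = 6) against 7.74 ± 6.78 CPM (SD, n = 5). The log2 difference was -4.26 (SE 0.91), with 6 of 6 High PA libraries below the Healthy mean. The ranges overlap, as High PA replicate 3, at 1.48 CPM, was above Healthy replicate 3, at 0.95 CPM. FTH1, the heavy chain of the iron store ferritin, on chromosome 11 from 61959718 to 61967660, was at 3080 ± 477 CPM (SD, n = 6) against 4740 ± 315 CPM (SD, n = 5), a log2 difference of -0.62 (SE 0.16).

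In edgeR 0 of 19648 genes were called higher and 0 lower in High PA than in Healthy. At an unadjusted p under 0.05 there were 2470 genes, 1387 higher and 1083 lower, where a share of 0.05 of the genes tested is about 982. DESeq2 called 5 genes, among them LEPR, PSCA and FTH1, and limma voom with sample quality weights called 1216, with a smallest adjusted p of 0.0463. The 1216 include 9 of the 12 genes above: LEPR, SEMA3C, INVS, ZDBF2, PSCA, ETV4, ME3, FTH1 and SNHG32. Leaving out High PA replicate 1 raised the count at an unadjusted p under 0.05 to 4884 and leaving out High PA replicate 6 lowered it to 1277, with 0 genes called in either case.

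SEMA3C, a secreted guidance protein, was at 34.3 ± 7.91 CPM (SD, n = 6) against 19.0 ± 3.88 CPM (SD, n = 5), and RGS5, a marker of pericytes and other cells of vessel walls, at 37.5 ± 9.21 CPM (SD, n = 6) against 21.7 ± 3.37 CPM (SD, n = 5). The log2 differences were 0.85 (SE 0.19) for SEMA3C, 0.79 (SE 0.21) for RGS5, 0.79 (SE 0.20) for INVS, 1.42 (SE 0.36) for ADAMTSL3 and 1.45 (SE 0.37) for ZDBF2. ME3, a mitochondrial malic enzyme, was at 22.2 ± 3.85 CPM (SD, n = 6) against 33.3 ± 2.17 CPM (SD, n = 5), a log2 difference of -0.58 (SE 0.15). The transcription factor ETV4 had a log2 difference of -1.10 (SE 0.27), GATD3B one of -1.08 (SE 0.28) and SNHG32 one of -0.57 (SE 0.15). GATD3B has a near-identical copy on the same chromosome, SNHG32 lies in the MHC region and FTH1 has many processed copies. LEPR shares 1.45% of its exonic bases with LEPROT on the same strand, and on the opposite strand PSCA shares 20.9% with JRK and FTH1 62.4% with BEST1, so the levels of these genes are uncertain.

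**Figure D2:**
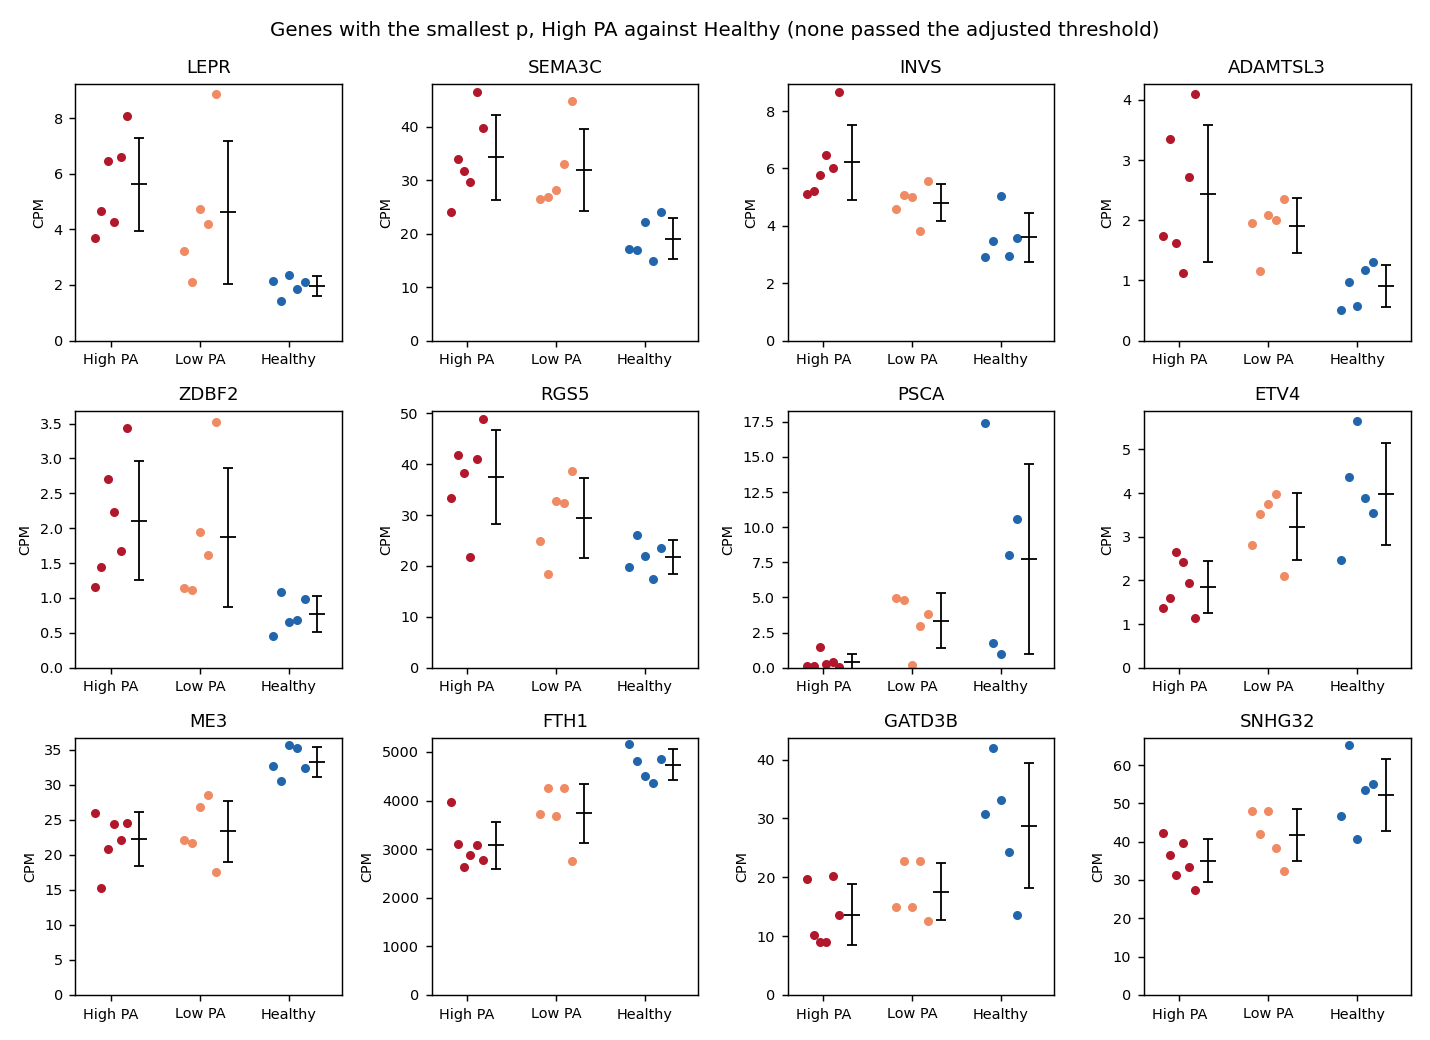
Each point is 1 library, placed by group on the horizontal axis, with its normalized expression in CPM on a vertical axis that starts at 0, and the bars give the mean and SD. LEPR averages 5.62 CPM in High PA and 1.97 CPM in Healthy, while none of the 12 genes passed the adjusted threshold (adjusted p = 0.387).

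Heat shock genes, whose products are protein-folding chaperones, had the smallest p among the lists in High PA against Healthy. Their mean log2 CPM was 6.17 ± 0.09 (SD, n = 6) in High PA and 6.46 ± 0.19 (SD, n = 5) in Healthy, with 6 of 10 members lower and 4 higher (fry, adjusted p = 0.374). HSPA1A was at 55.6 ± 9.11 CPM (SD, n = 6) against 94.2 ± 24.0 CPM (SD, n = 5), a log2 difference of -0.76 (SE 0.20). It was the 1 member under the threshold when adjusted over the list alone (adjusted p = 0.0153), against 0 members over all genes tested, and it shares sequence with HSPA1B, at -0.68 (SE 0.26). The small heat shock gene HSPB1 had a log2 difference of -0.73 (SE 0.28).

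All 23 ribosomal protein genes were lower in High PA than in Healthy, at 9.32 ± 0.35 (SD, n = 6) against 9.88 ± 0.40 (SD, n = 5) mean log2 CPM, and the list did not pass (fry, adjusted p = 0.374). Adjusted over the list alone, 23 members were under the threshold, and over all genes tested 0. These short transcripts stand beside the length correlation above, which differed between the same groups by 0.409. RPL13 was at 1090 ± 450 CPM (SD, n = 6) against 1770 ± 506 CPM (SD, n = 5).

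Genes of proliferating cells were higher in High PA for 17 of 18 members, with 8 under the threshold adjusted over the list alone and 0 over all genes tested (fry for the list, adjusted p = 0.684). The libraries were not alike in this. High PA replicates 6 and 2 were the highest, at 4.89 and 4.37 mean log2 CPM, and replicates 5 and 3 were at 3.88 and 3.69. Replicates 1 and 4, at 3.41 and 3.26, lay within the Healthy range of 3.20 to 3.56. TOP2A, the topoisomerase of dividing cells, was at 27.0 ± 18.1 CPM (SD, n = 6) against 11.2 ± 2.11 CPM (SD, n = 5), and CDK1, the kinase that drives mitosis, at 11.3 ± 5.70 CPM (SD, n = 6) against 5.25 ± 0.864 CPM (SD, n = 5). Tuft cell genes were lower for 8 of 9 members (fry, adjusted p = 0.476), and POU2F3, TRPM5 and SH2D6 were the 3 under the threshold adjusted over the list alone (adjusted p = 0.0307 for each), with 0 over all genes tested. POU2F3, the transcription factor of the tuft cell lineage, was at 0.841 ± 0.273 CPM (SD, n = 6) against 2.37 ± 1.56 CPM (SD, n = 5). Haemoglobin and other red blood cell genes were lower for 3 of 3 members, by a mean log2 difference of -1.16 (fry, adjusted p = 0.374). Of these, 2 were under the threshold adjusted over the list alone and 0 over all genes tested. The list of serotonin and visceral sensing genes was higher for 11 of 13 members, with 0 under the threshold adjusted over the list alone (fry, adjusted p = 0.374).

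Among the lists that bear on proteases and the barrier, none passed in High PA against Healthy. Tight junction genes were higher for 11 of 18 members (fry, adjusted p = 0.689), with TJP1, which codes for the scaffold protein ZO-1, at 75.5 ± 33.4 CPM (SD, n = 6) against 42.0 ± 20.3 CPM (SD, n = 5). TJP1 had a log2 difference of 0.85 (SE 0.36), occludin (OCLN) one of 0.68 (SE 0.39) and MARVELD2 one of 0.28 (SE 0.16). Cell-surface mucins were split, with 3 of 7 higher (fry, adjusted p = 0.958), a mean log2 fold change of 0.09 and a median of -0.06, which differ in sign. MUC17, a membrane mucin of the colonocyte surface, was at 57.9 ± 19.0 CPM (SD, n = 6) against 26.6 ± 16.8 CPM (SD, n = 5), a log2 difference of 1.12 (SE 0.34) that passed adjusted over the list alone (adjusted p = 0.0278) but not over all genes tested (adjusted p = 0.387). Weighted limma voom called MUC17, at a log2 difference of 1.73, and TJP1, at 0.98 (adjusted p = 0.0463 for each), and voom called 0 genes without the weights. MUC3A had a log2 difference of -0.32 (SE 0.14), MUC4 one of -0.15 (SE 0.30) and MUC1 one of -0.17 (SE 0.33).

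Serine protease genes were higher for 8 and lower for 8 of 16 members (fry, adjusted p = 0.958), and PRSS8, which codes for prostasin of epithelial membranes, was at 427 ± 167 CPM (SD, n = 6) against 543 ± 116 CPM (SD, n = 5). The pancreatic-type elastases CELA3A and CELA3B were near or under 1 CPM in both groups, with log2 differences of 1.43 (SE 0.76) and 0.90 (SE 0.72), and PRSS3 had one of -0.26 (SE 0.20). Protease inhibitors were higher for 10 and lower for 10 of 20 members (fry, adjusted p = 0.958). WFDC2 had a log2 difference of -0.73 (SE 0.36), SPINT1 one of -0.31 (SE 0.18), CST3 one of -0.40 (SE 0.27) and TFPI one of 0.31 (SE 0.22). The mean log2 fold change of this list, -0.01, differed in sign from its median, 0.06, and from the difference of its group means, 0.01.

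The protease-activated receptors, through which proteases signal to cells, were higher for 2 of 4 members (fry, adjusted p = 0.689). F2R had a log2 difference of 0.40 (SE 0.24), F2RL1 one of 0.36 (SE 0.31), F2RL2 one of -0.41 (SE 0.47) and F2RL3 one of -0.03 (SE 0.36). Mast cell genes were higher for 5 of 9 members (fry, adjusted p = 0.857), with log2 differences of 0.71 (SE 0.34) for KIT, 0.58 (SE 0.48) for MS4A2, 0.29 (SE 0.27) for GATA2 and 0.39 (SE 0.43) for CPA3. Glucuronidation genes, whose products attach glucuronic acid to bilirubin and drugs, were higher for 8 of 11 members (fry, adjusted p = 0.684). UGT2A3 had a log2 difference of 0.79 (SE 0.39), and UGT1A10, UGT1A8 and UGT1A1 ones of 0.54 (SE 0.29), 0.47 (SE 0.29) and 0.49 (SE 0.31). The UGT1A genes share exons, so their counts are not independent.

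**Figure D3:**
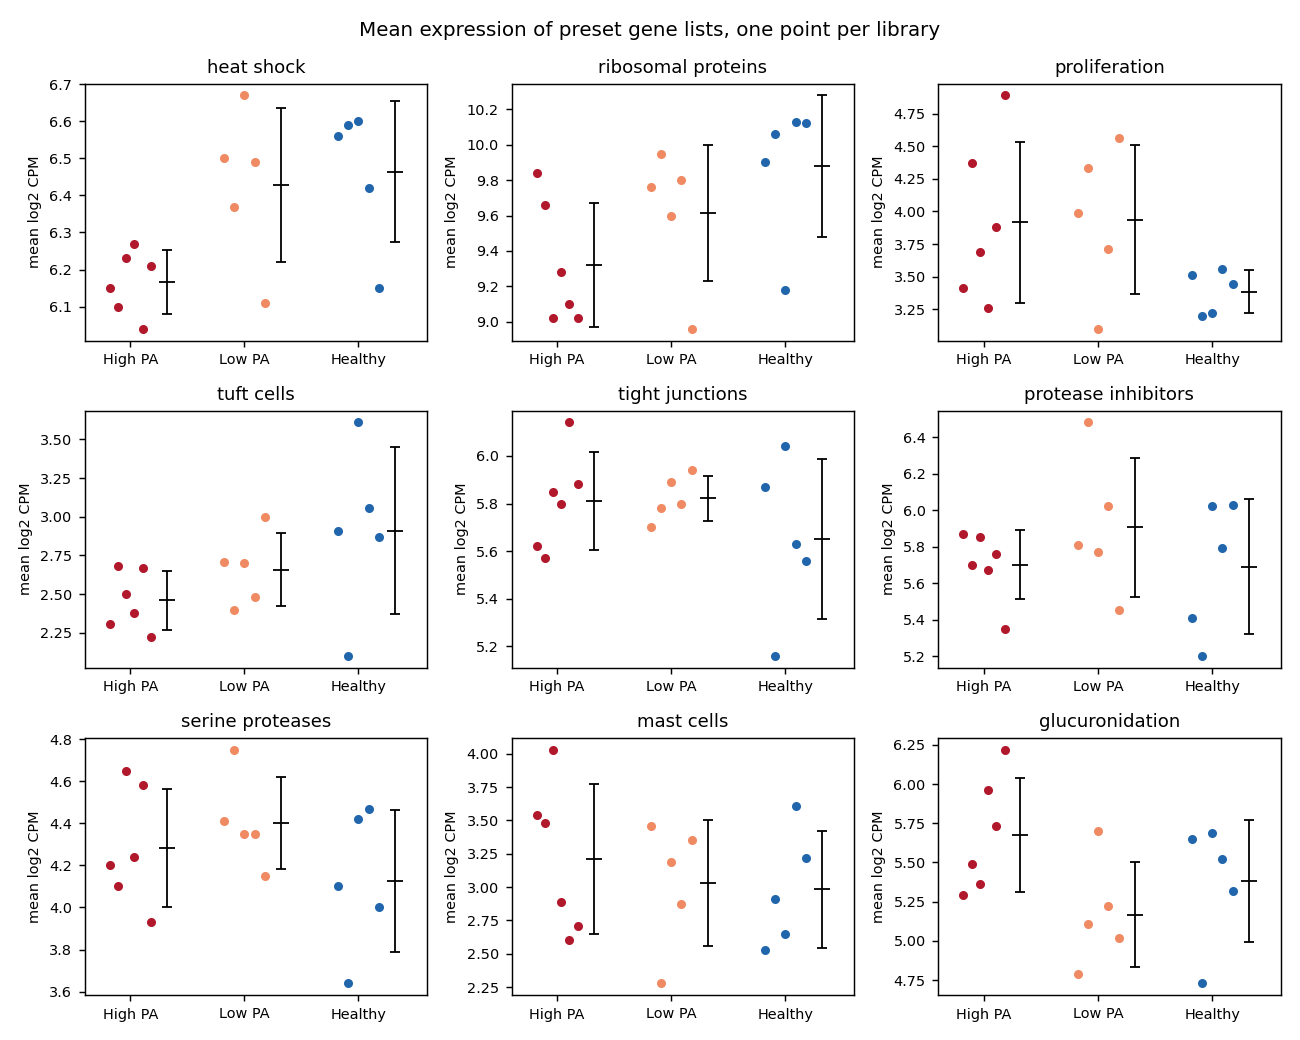
Each point is the mean log2 CPM of a preset gene list in 1 library, with groups on the horizontal axis and bars for the group mean and SD. The heat shock list averages 6.17 in High PA, 6.43 in Low PA and 6.46 in Healthy, the proliferation list 3.92, 3.94 and 3.39, and none of these lists passed the adjusted threshold.

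The comparison of High PA with Low PA asks what differs within the disease. The genes with the smallest p were higher in High PA for ENOSF1, ACOX2, COL17A1, SORL1, PAX8 and PBLD and lower for CLEC10A, ACP5, CMKLR1, PLTP, GNGT2 and PSCA, and none passed (edgeR quasi-likelihood test, adjusted p = 1 for each). CLEC10A, a lectin of dendritic cells and macrophages, on chromosome 17 from 7074537 to 7080307, was at 12.9 ± 2.83 CPM (SD, n = 6) in High PA and 23.4 ± 6.89 CPM (SD, n = 5) in Low PA. The log2 difference was -0.86 (SE 0.20), with 6 of 6 High PA libraries below the Low PA mean. ACP5, the tartrate-resistant acid phosphatase of macrophages and osteoclasts, on chromosome 19 from 11574660 to 11579008, was at 59.7 ± 12.9 CPM (SD, n = 6) against 110 ± 40.0 CPM (SD, n = 5), a log2 difference of -0.88 (SE 0.20). COL17A1, a collagen of hemidesmosomes, on chromosome 10 from 104031286 to 104086002, was at 199 ± 23.5 CPM (SD, n = 6) against 121 ± 39.1 CPM (SD, n = 5), a log2 difference of 0.72 (SE 0.20).

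Of 19648 genes, edgeR called 0 and DESeq2 and weighted limma voom also 0 between High PA and Low PA. There were 448 genes at an unadjusted p under 0.05, fewer than 982, a share of 0.05 of the genes tested, and 1914 in weighted voom. Log2 differences were 0.50 (SE 0.13) for ENOSF1, 0.68 (SE 0.19) for ACOX2, 0.71 (SE 0.20) for SORL1, 1.18 (SE 0.37) for PAX8 and 0.73 (SE 0.23) for PBLD. They were -0.55 (SE 0.15) for the chemerin receptor CMKLR1, -0.57 (SE 0.16) for PLTP, -0.92 (SE 0.27) for GNGT2 and -3.05 (SE 0.89) for PSCA. On the opposite strand ENOSF1 shares 8.48% of its exonic bases with TYMS and PAX8 9.26% with PAX8-AS1, so both are uncertain. That count was 1368 without Low PA replicate 5 and 691 without High PA replicate 1. Leaving out High PA replicate 3 gave 1 call (adjusted p = 0.0234), of a gene in the class that is not named.

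Macrophage genes were lower in High PA than in Low PA for 9 of 9 members (fry, adjusted p = 0.756), at 5.49 ± 0.31 (SD, n = 6) against 5.81 ± 0.24 (SD, n = 5) mean log2 CPM. MHC class II presentation genes were lower for 8 of 9 (fry, adjusted p = 0.756), at 6.66 ± 0.32 (SD, n = 6) against 7.08 ± 0.13 (SD, n = 5). C1QB of the complement system was at 111 ± 28.6 CPM (SD, n = 6) against 152 ± 17.6 CPM (SD, n = 5), and IFI30, a lysosomal reductase of antigen processing, at 100 ± 17.1 CPM (SD, n = 6) against 146 ± 31.0 CPM (SD, n = 5). Heat shock genes were lower for 9 of 10 members (fry, adjusted p = 0.630), and unfolded protein response genes for 11 of 14 (fry, adjusted p = 0.756). In these 4 lists 0 members were under the threshold, whether adjusted over the list alone or over all genes tested.

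The protease and barrier lists did not pass between High PA and Low PA. Tight junction genes were higher for 11 of 18 members (fry, adjusted p = 0.957), a list whose mean log2 fold change of -0.03 and median of 0.06 differed in sign. CLDN1 had a log2 difference of -0.97 (SE 0.46), CLDN2 one of -1.03 (SE 0.68), MARVELD3 one of 0.23 (SE 0.18) and CGN one of 0.27 (SE 0.24). Cell-surface mucins were higher for 3 of 7 (fry, adjusted p = 0.995), and their mean log2 fold change of 0.09 and median of -0.07 differed in sign. The log2 differences were -0.33 (SE 0.14) for MUC3A, 0.63 (SE 0.34) for MUC17, 0.74 (SE 0.40) for MUC20 and -0.21 (SE 0.33) for MUC1. Serine proteases were higher for 7 of 16 (fry, adjusted p = 0.957), with -0.51 (SE 0.41) for ELANE, 0.20 (SE 0.19) for PLAT, -0.77 (SE 0.75) for PRSS22 and 0.17 (SE 0.17) for TMPRSS4.

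Protease inhibitors were lower in High PA than in Low PA for 18 of 20 members (fry, adjusted p = 0.935), with 0 under the threshold adjusted over the list alone. Low PA replicate 2 was the highest, at 6.48 mean log2 CPM. The other Low PA libraries lay between 5.45 and 6.02, and the High PA libraries between 5.35 and 5.87. SPINK1, a trypsin inhibitor, was at 98.2 ± 25.5 CPM (SD, n = 6) against 153 ± 89.5 CPM (SD, n = 5), a log2 difference of -0.64 (SE 0.31). TFPI2 had one of -0.69 (SE 0.44), WFDC2 one of -0.56 (SE 0.36) and SERPINA3 one of -0.65 (SE 0.49). Protease-activated receptors were higher for 2 of 4 (fry, adjusted p = 0.935), with -0.73 (SE 0.46) for F2RL2, -0.31 (SE 0.24) for F2R, 0.12 (SE 0.36) for F2RL3 and 0.02 (SE 0.31) for F2RL1. Mast cell genes were higher for 7 of 9 (fry, adjusted p = 0.935), with 0.33 (SE 0.36) for TPSB2, 0.60 (SE 0.71) for CMA1, 0.25 (SE 0.34) for HDC and 0.18 (SE 0.27) for GATA2. Glucuronidation genes were higher for 9 of 11 (fry, adjusted p = 0.935), with 0.47 (SE 0.37) for UGT2B7, 0.36 (SE 0.29) for UGT1A10, 0.34 (SE 0.29) for UGT1A8 and 0.32 (SE 0.29) for UGT1A6.

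The comparison of Low PA with Healthy sets disease against health between groups that are both labelled Low PA. The genes with the smallest p were higher in Low PA for FGL2, TDO2, GPR180, OSGIN2, FBN1 and TWSG1 and lower for ACSM1, DEF8, PRELID3A, CHST13, CCDC183 and ZNF839, and none passed (edgeR quasi-likelihood test, adjusted p = 0.683 for each). FGL2, a fibrinogen-like protein of macrophages and T cells, on chromosome 7 from 77193371 to 77199826, was at 81.7 ± 28.1 CPM (SD, n = 5) in Low PA and 41.5 ± 4.56 CPM (SD, n = 5) in Healthy. This is a fold of 1.97 (log2 0.98, SE 0.22), with 5 of 5 Low PA libraries above the Healthy mean. FBN1, the microfibril protein fibrillin, on chromosome 15 from 48408306 to 48645849, was at 22.7 ± 6.82 CPM (SD, n = 5) against 11.5 ± 2.64 CPM (SD, n = 5), a log2 difference of 0.98 (SE 0.26). ACSM1, an enzyme that activates medium-chain fatty acids, on chromosome 16 from 20623237 to 20698890, was at 0.648 ± 0.225 CPM (SD, n = 5) against 2.32 ± 0.920 CPM (SD, n = 5), a log2 difference of -1.84 (SE 0.42).

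Between Low PA and Healthy edgeR called 0 of 19648 genes, as did DESeq2 and weighted limma voom. There were 1354 genes at an unadjusted p under 0.05, where a share of 0.05 of the genes tested is about 982. With the immediate early level as a covariate there were 876, and without the 5 libraries high in immediate early genes 908. Log2 differences were 1.56 (SE 0.39) for TDO2, which degrades tryptophan, 0.80 (SE 0.21) for GPR180, 0.61 (SE 0.16) for OSGIN2 and 0.82 (SE 0.22) for TWSG1. They were -0.51 (SE 0.13) for DEF8, -1.0 (SE 0.26) for PRELID3A, -1.90 (SE 0.51) for CHST13, -0.81 (SE 0.22) for CCDC183 and -0.60 (SE 0.16) for ZNF839. Without Low PA replicate 5 the count at an unadjusted p under 0.05 was 670, and without Low PA replicate 2 it was 2396.

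Fibroblast genes were higher in Low PA than in Healthy for 11 of 12 members (fry, adjusted p = 0.606), at 5.95 ± 0.31 (SD, n = 5) against 5.62 ± 0.25 (SD, n = 5) mean log2 CPM. LUM, a proteoglycan of connective tissue, was at 135 ± 53.2 CPM (SD, n = 5) against 73.3 ± 17.6 CPM (SD, n = 5) and was the 1 member under the threshold adjusted over the list alone (adjusted p = 0.0308), with 0 over all genes tested. Macrophage genes were higher for 8 of 9 members (fry, adjusted p = 0.606), with MS4A7 the 1 member that passed adjusted over the list alone (adjusted p = 0.0439). Proliferation genes were higher for 18 of 18 members (fry, adjusted p = 0.606), with 2 under the threshold adjusted over the list alone, CDK1 and CCNB1, and 0 over all genes tested. Low PA replicate 3, at 3.10 mean log2 CPM, was nevertheless below every Healthy library, and the other Low PA libraries were above them all. Red blood cell genes were lower for 3 of 3 members (fry, adjusted p = 0.606).

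Low PA and Healthy did not differ beyond the threshold in the protease and barrier lists. The thrombin receptor F2R was at 11.7 ± 4.84 CPM (SD, n = 5) against 7.16 ± 1.24 CPM (SD, n = 5), a log2 difference of 0.71 (SE 0.25). It passed adjusted over the list alone (adjusted p = 0.0492) but not over all genes tested (adjusted p = 0.683), and the receptors as a list did not pass (3 of 4 higher, fry, adjusted p = 0.606). F2RL1 had a log2 difference of 0.33 (SE 0.32), F2RL2 one of 0.31 (SE 0.48) and F2RL3 one of -0.15 (SE 0.38). Tight junction genes were higher for 9 of 18 members (fry, adjusted p = 0.869), with 1.65 (SE 0.74) for CLDN2, a claudin that forms a cation pore, 0.77 (SE 0.37) for TJP1, -0.43 (SE 0.23) for CLDN15 and -0.43 (SE 0.28) for CLDN3. CLDN2 was low, at 1.02 ± 1.24 CPM (SD, n = 5) against 0.308 ± 0.257 CPM (SD, n = 5).

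Protease inhibitors were higher in Low PA than in Healthy for 13 of 20 members (fry, adjusted p = 0.837), with 1.11 (SE 0.47) for TFPI2, 0.44 (SE 0.23) for TFPI, 0.27 (SE 0.17) for A2M and -0.45 (SE 0.28) for CST3. Serine proteases were higher for 8 of 16 (fry, adjusted p = 0.869), and their mean log2 fold change of 0.21 and median of -0.03 differed in sign. The log2 differences were 1.45 (SE 0.77) for CELA3A, 1.21 (SE 0.75) for CELA3B, -0.40 (SE 0.26) for PRSS8 and 0.93 (SE 0.79) for PRSS22. Mast cell genes were higher for 5 of 9 (fry, adjusted p = 0.925), with 0.61 (SE 0.35) for KIT, -0.58 (SE 0.38) for TPSB2, 0.43 (SE 0.45) for CPA3 and -0.62 (SE 0.74) for CMA1. Cell-surface mucins were higher for 5 of 7 (fry, adjusted p = 0.925), with 0.50 (SE 0.35) for MUC17, -0.58 (SE 0.41) for MUC20, 0.04 (SE 0.35) for MUC1 and 0.01 (SE 0.15) for MUC3A. Glucuronidation genes were higher for 8 of 11 (fry, adjusted p = 0.925), with a mean log2 fold change of 0.04 but a difference of group means of -0.22. The log2 differences were 0.64 (SE 0.38) for UGDH, -0.60 (SE 0.39) for UGT2B7, 0.45 (SE 0.40) for UGT2A3 and 0.13 (SE 0.18) for UGP2.

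The last comparison sets the average of both patient groups against Healthy. A change in a single patient group can drive it, so it does not show that a change is common to both. LEPR, SEMA3C and CTSE were the higher and ACSM1, ZNF839 and ME3 the lower genes with the smallest p, and none passed (edgeR quasi-likelihood test, adjusted p = 0.402 for each). LEPR was above the Healthy mean in 11 of 11 patient libraries, with a log2 difference of 1.37 (SE 0.30), and SEMA3C in 11 of 11, with 0.80 (SE 0.17). Both were picked by p in these libraries, so these counts follow in part from that choice. LEPR in Low PA replicate 2, at 2.10 CPM, was below Healthy replicate 3, at 2.35 CPM. CTSE, the protease cathepsin E, on chromosome 1 from 206009264 to 206023909, was at 52.9 ± 2.81 CPM (SD, n = 6) in High PA and 52.6 ± 5.26 CPM (SD, n = 5) in Low PA against 35.9 ± 8.53 CPM (SD, n = 5) in Healthy, a log2 difference of 0.55 (SE 0.14). The log2 differences were -1.39 (SE 0.33) for ACSM1, -0.57 (SE 0.14) for ZNF839 and -0.55 (SE 0.13) for ME3.

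For the patients as a whole edgeR called 0 of 19648 genes, with 2414 at an unadjusted p under 0.05 and a smallest adjusted p of 0.402. DESeq2 called 1 gene, LEPR, and weighted limma voom 0. None of the 50 lists passed (fry, smallest adjusted p = 0.481). The count at an unadjusted p under 0.05 was 4337 without High PA replicate 1, 3749 without Low PA replicate 2 and 1599 without Low PA replicate 5.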

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

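The tests of the immediate early level, of composition against the unadjusted counts and of the order and group of the samples were chosen after the results were seen. The corrections for gene length and GC percent and voom without weights were added after seeing the data.

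High PA against Healthy gave 2470 genes at an unadjusted p under 0.05, and none passed in edgeR. A share of 0.05 of the genes tested is about 982, so the excess over it was 1488. In 4 of 100 splits of the same libraries, the real one included, there were as many genes. The other splits had a median of 672 genes and 6311 in the highest. Few splits thus reached the real count, from 1 draw among 462 possible splits in 1 of the 4 comparisons. That share was not adjusted over the comparisons, and no splits were run without High PA replicate 6, where the count was 1277. Chance is therefore not excluded. Among the splits other than the real one 4 had genes called, up to 2803, which points to a structure of these libraries. With 1 surrogate variable, a factor estimated from the data, the groups gave 697 genes, an excess of -285. The splits, with their median of 672, were run without that factor. What that factor stands for was not tested. With the immediate early level as a covariate 0.858 of the excess was left. That level averaged 5.19 mean log2 CPM in High PA and 5.60 in Healthy, so this covariate had little group difference to remove. The share left cannot decide whether the immediate early level plays a part. With the composition score 1.26 was left, more than the whole. That score averaged 3.02 in both groups, so the covariate had little to remove, and it holds no immune cell genes. It cannot decide whether biopsy composition in general plays a part. After the correction for gene length and GC percent 0.661 of the excess was left, between the bounds set before that value was seen. This trend and the disease group therefore cannot be told apart as sources, and a biological difference stays open. The labels give neither the sex of the volunteers nor the site of the biopsies in the colon, so neither was adjusted for.

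Chance is not excluded for the other comparisons either. The median over the splits other than the real one was 732 genes in High PA against Low PA, 790 in Low PA against Healthy and 599 in PI-IBS against Healthy. High PA against Low PA gave 448 genes at an unadjusted p under 0.05, and 68 of 100 splits gave as many, the highest other 5580, while 5 splits had genes called, up to 1313. Low PA against Healthy gave 1354, and 19 of 100 splits gave as many, the highest other 3813, and 2 splits had genes called, at most 1. PI-IBS against Healthy gave 2414, and 11 of 100 splits gave as many, the highest other 4984, and 2 splits had genes called, at most 1. The highest number of calls in a split was thus 2803 in High PA against Healthy and 1313 in High PA against Low PA, and at most 1 in these last 2. Whether the High PA libraries account for this was not tested.

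Limma voom with sample quality weights called 1216 genes in High PA against Healthy, of which 966 were at an unadjusted p under 0.05 in the same direction in edgeR. The weights ranged from 0.36, for High PA replicate 1, to 2.10, for Healthy replicate 5. Voom called 0 genes without the weights (smallest adjusted p = 0.418) and 0 with the weights and the length and GC correction (smallest adjusted p = 0.13). Over the 1216 genes the median log2 difference in the direction of the call was 0.68 (quartiles 0.56 and 0.85), with the correction 0.43 (0.28 and 0.66) and without weights 0.56 (0.46 and 0.70). The calls ended with smaller differences, while 976 and 1012 of the genes were still at an unadjusted p under 0.05 in the same direction. The genes were picked by weighted voom in the same libraries, so these counts and the smaller differences follow in part from that choice. They cannot decide whether the groups differ, which stays open.

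Immediate early genes were high in 5 of the 16 libraries: High PA replicates 1 and 2, Low PA replicate 1, and Healthy replicates 1 and 2. FOS lay between 271 and 850 CPM in these and between 8.41 and 72.1 CPM in the other 11 libraries, and EGR1 between 258 and 585 CPM against 4.12 to 33 CPM. Each of the 3 groups holds libraries of both levels, which argues against the group as the cause. The 5 libraries are the first 5 of the series' sample list, which a random draw of 5 of 16 gives with an exact share of 0.000229. This test was chosen after the pattern was seen, so its share only describes the pattern. A step of collection or handling that changed over time may lie behind these libraries. The labels give no date or batch, so that stays a hypothesis.

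The remaining results stood out because 1 library lay far from the rest of its group, by the gap to its nearest neighbour divided by the range of the group. Of 423 groups of values tested, 24 stood out in this way, where chance gives about 21. Among library measures these were the immediate early level in Low PA (0.778, the highest at 6.92 against 4.57 mean log2 CPM) and the ribosomal protein level in Healthy (0.764, the lowest at 9.18 against 9.90). Among lists they were goblet cells in Healthy (0.858, the lowest at 6.25 against 8.32 mean log2 CPM), neutrophils in Healthy (0.751) and type I interferon response in Healthy (0.800), all at the low end. Fibroblasts (0.829) and the mitochondrial genome (0.735) stood out at the low end in Low PA. Matrix metalloproteinases and TIMPs (0.749) and type I interferon response (0.633) stood out at the high end in High PA.

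Among genes the lowest library stood out for GNGT2 (0.677) and PRELID3A (0.628) in High PA and for ADAMTSL3 (0.734), PSCA (0.832), PBLD (0.768), PRSS8 (0.724), SPINT1 (0.790) and F2RL2 (0.737) in Low PA. It also did for CTSE (0.729) and UGP2 (0.815) in Healthy. The highest library stood out for CMA1 (0.669) in High PA, for GPR180 (0.715) and DEF8 (0.763) in Low PA, and for MUC4 (0.786) and PRSS8 (0.730) in Healthy.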

How the results depend on the processing

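The corrections for length and GC percent, voom without weights, the immediate early covariate and the fit without 5 libraries were chosen after seeing the data. EdgeR called 0 genes in each of the 4 comparisons with other size factors, filters, dispersions or covariates, with 1 surrogate variable and at an adjusted p under 0.1, and limma-trend on FPKM values called 0 too. With only the groups compared, run for the 3 pairwise comparisons, edgeR called 0. High PA against Healthy had 5 calls in DESeq2, 1216 in weighted voom (535 higher and 681 lower) and 1 without the 5 libraries high in immediate early genes. PI-IBS against Healthy had 1 call in DESeq2. Leaving out each library in turn gave 0 to 0 calls, except 0 to 1 in High PA against Low PA, where the call came without High PA replicate 3. The DESeq2 calls were LEPR (log2 1.51), PSCA (-4.28), FTH1 (-0.63) and 2 genes in the classes that are not named. Why the tools differ was tested for voom alone, and for the other calls the cause was not tested.

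Genes at an unadjusted p under 0.05 in High PA against Healthy numbered 697 with 1 surrogate variable, 1965 with the length and GC correction, 2958 without the 5 libraries, 3762 of 36045 without a filter and 5658 in weighted voom. The main edgeR fit gave 2470, and a share of 0.05 of the genes tested there is about 982. With the surrogate variable PI-IBS against Healthy had 761 against 2414, Low PA against Healthy 784 against 1354 and High PA against Low PA 796 against 448. Weighted voom gave 4927, 2500 and 1914 in the same order, and with the length and GC correction as well 3169, 1855 and 1345. Low PA against Healthy had 876 with the immediate early covariate and 908 without the 5 libraries. Both are fewer than 982 but more than 790, the median over the other splits of these libraries in the main fit.

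Fry called 0 lists in each comparison and alternative fit, except that leaving out each library gave 0 to 1 in High PA against Healthy, where heat shock passed without Healthy replicate 5 (adjusted p = 0.0482). Camera with the preset correlation called 9 lists in High PA against Healthy, 15 in High PA against Low PA, 10 in Low PA against Healthy and 10 in PI-IBS against Healthy, and with an estimated correlation 0 in each (smallest adjusted p = 0.886, 0.186, 0.757 and 0.872). No paired analysis was possible because replicate numbers only name the libraries.

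Of 2381 alternative values of the 126 named gene results, 2297 kept direction and side of the threshold, 15 passed it and 69 changed sign, none of the last past a threshold, and the cause was not tested. Values in parentheses give the range when each library is left out in turn. In High PA against Healthy the log2 differences that changed sign were 0.20, 0.15, 0.10, 0.17, 0.20, 0.52, 0.05, 0.20, 0.34 and 0.26 (-0.22 to 0.26) for F2RL3, 0.20, 0.08, 0.08, 0.02 and 0.31 (-0.30 to 0.31) for MUC4, 0.36, 0.07 and 0.01 for MUC1, 0.08, 0.05 and 0.37 (-0.64 to 0.37) for F2RL2, and 0.03 for PRSS3. They were -0.17 for MS4A2, -0.05 for GATA2, -0.07 and -0.04 for CPA3, -0.12 for TFPI, and, with the surrogate variable, -0.14 for OCLN, 0.01 for CST3, -0.09 for F2R, -0.14 for F2RL1 and -0.04 for UGT2A3. In High PA against Low PA they were -0.17, -0.15, -0.03, -0.04, -0.03 and -0.09 (-0.09 to 0.16) for F2RL1, -0.03, -0.04 and -0.07 (-0.07 to 0.27) for F2RL3, -0.07 for TPSB2, -0.08 (-0.08 to 0.38) for HDC, 0.06 (-1.59 to 0.06) for CLDN2 and 0.14 (-0.53 to 0.14) for MUC1. In Low PA against Healthy they were 0.23, 0.04, 0.04, 0.10, 0.11, 0.43, 0.24, 0.29 and 0.15 (-0.32 to 0.15) for F2RL3, -0.05, -0.01, -0.10 and -0.31 (-0.31 to 0.23) for MUC1, -0.08, -0.12 and -0.01 (-0.01 to 0.20) for UGP2, -0.02 and -0.06 (-0.06 to 0.08) for MUC3A, 0.10 and 0.77 (-1.07 to 0.77) for CMA1, 0.08 for CLDN3, -0.19 for F2RL2 and -0.24 for UGT2A3. Of 349 list values 13 changed sign: mast cells at -0.16 and -0.03 (-0.03 to 0.42) and protease inhibitors at 0.04, 0.01 and 0.10 (-0.08 to 0.10) in High PA against Healthy, mast cells at -0.03 (-0.03 to 0.28), tight junctions at 0.01 and 0.02 (-0.09 to 0.02) and serine proteases at 0.03 (-0.17 to 0.03) in High PA against Low PA, and glucuronidation at -0.07, -0.03, -0.02 and -0.10 (-0.10 to 0.15) in Low PA against Healthy. At these depths the median SE of the log2 difference was 0.20 in High PA against Healthy for genes above 2 mean log2 CPM. Of the simulated 2-fold changes 41% were recovered there, in counts without the shared trends of the real libraries.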

Other observations

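Cell types and regions of the colon that the comparisons did not turn on differed widely between single biopsies. B cell genes had the widest range of all lists, from -0.61 to 4.74 mean log2 CPM, with 2.09 ± 1.60 (SD, n = 6) in High PA, 3.01 ± 0.35 (SD, n = 5) in Low PA and 1.94 ± 2.15 (SD, n = 5) in Healthy. Distal colon position genes, mainly HOX genes and PRAC1, spanned 2.85 log2 units, from 2.71 to 5.57, with group means of 4.47 ± 0.71 (SD, n = 6), 4.24 ± 0.95 (SD, n = 5) and 4.21 ± 1.19 (SD, n = 5). Goblet cell genes spanned 2.41 log2 units and enteroendocrine genes 2.41. None of these 4 lists passed in any of the 4 comparisons (fry, for goblet cells in PI-IBS against Healthy adjusted p = 0.98).

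Enteroendocrine genes were higher in High PA than in Healthy for 14 of 15 members (fry, adjusted p = 0.684) and cholesterol synthesis genes for 13 of 14 (fry, adjusted p = 0.684). Type I interferon genes were higher in Low PA than in Healthy for 15 of 18 members (fry, adjusted p = 0.606). AZGP1, a zinc-binding secreted glycoprotein, on chromosome 7 from 99966720 to 99976157, was the 1 gene called in High PA against Healthy without the 5 libraries high in immediate early genes, with a log2 difference of -1.80 (edgeR, adjusted p = 0.0355). That fit, chosen after seeing the data, lacks High PA replicates 1 and 2, Low PA replicate 1 and Healthy replicates 1 and 2. With all 16 libraries edgeR called 0 genes in this comparison. AZGP1 is named after its value was seen.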
